A study of Homo sapiens with 2 samples.

How the data were processed

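Poly(A)-selected RNA of MCF-7 and MDA-MB-435S cells was measured by sequencing on an Illumina Genome Analyzer IIx, with 1 library per line. Per the labels' protocols, both lines were grown in DMEM with fetal bovine serum and antibiotics, RNA was extracted with Trizol and libraries were made with the TruSeq mRNA kit. The growth protocol writes MDA-MB-435, while the title and the cell line label of the sample write MDA-MB-435S, and the sample label is used here. Per the labels' design text, the authors mapped the reads to RefSeq RNA sequences, and per the labels reads that passed the Illumina filter were kept. The submitters' processing notes name CASAVA 1.8 and the builds GRCh37 and hg19, with no role given. The mapping program, the strand setting and the treatment of reads that map to several genes are not given in the sources used here.

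Each library's deposited table holds 1 row per gene with a RefSeq identifier, a gene symbol, a length, a read count and an RPKM value, per the file headers. The deposited counts are whole numbers and are not normalized. The deposited RPKM, which divides a count by transcript length and library size, equals the value computed from the count, the length and the library total within a relative difference of 5.42e-07, so it holds no further information and the counts were used. The tables have 23709 rows, of which 18646 carry an identifier of a coding message and 5063 that of a non-coding RNA. Some coding genes, such as KRT8 and SERPINE2, carry an identifier of the second kind, so 5063 is not a count of non-coding genes. Transcripts under 100 bases make up 1426 rows and are not well recovered by this kind of library. In 26 rows the symbol had been turned into a date, 24 of these were restored by identifier, and 2 are named by their identifier. Rows for XIST, TSIX and Y-linked genes, 102 in all, were left out of the ratios, calls and lists, which used 23607 rows. They stayed in the library totals, the scaling, the read shares and the numbers of genes with reads. Identifiers of 22865 rows matched the RefSeq gene table of assembly GRCh38.p14. Because that assembly differs from the builds named by the submitters, it served only for names and for which genes neighbour each other, and no coordinates are given.

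Counts were scaled between the libraries with the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3. CPM is the count over the scaled library total. The log2 ratio of MDA-MB-435S over MCF-7 was taken on the log2(CPM + 1) scale, while folds named for single genes are ratios of scaled CPM without a pseudocount. A gene was called higher or lower where its log2 ratio was at least 1 in size and the higher library held at least 50 reads. These rules, the gene lists and the rule for named genes were fixed before the data were examined. A gene with at most 1 read in both libraries counted as not detected, which left 20023 detected genes. Levels have exact Poisson and ratios exact conditional binomial 95% intervals, and shares of reads have exact Clopper-Pearson intervals. Reads without molecular identifiers are not independent molecules, so these intervals and the floors cover counting error only, unlike the intervals of medians below. The floor of 3 counts corresponds to 0.215 CPM in MCF-7 and 0.177 CPM in MDA-MB-435S. No count model or p-value across genes was used, since 1 library per line gives no spread.

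The 27 gene lists hold 750 entries, or 718 distinct genes, all of which matched the tables, 3 of them by an older symbol. They cover luminal, basal mammary, melanocyte, neural crest, epithelial and mesenchymal genes, proteases, integrins, receptor kinases, MHC class I and II, interferon-stimulated, cancer-testis, cell cycle, p53 target, ERK output, glycolysis, respiratory chain, cholesterol, ribosomal protein and histone genes, genes of 17q23 and 20q13 and of 9p21, markers of leukocytes, endothelium and fibroblasts, and reference genes. For each list the median log2 ratio of the detected genes is given with an order-statistic 95% interval, except for the 3 genes of 9p21, which are too few for such an interval and have their range. Its percentile among 10000 random lists of the same size, matched on mean expression in 10 bins, describes these libraries and is not a test across samples. The named genes are the 10 with the largest log2 ratio in each direction among called genes, up to 4 called members per list with the largest log2 ratio in size, and a set fixed whatever its values, namely ESR1, GATA3, KRT18, CDH1, EPCAM, VIM, CDH2, MITF, SOX10, PMEL, MLANA, TYR, S100B, CDKN2A, MTAP, TP53, MKI67, ERBB2, EGFR, CD44, ACTB and GAPDH.

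Alternatives were scaling to library totals, by the median of ratios of DESeq2 1.42.0, by the upper quartile and by TMM without the 100 most abundant genes, a pseudocount of 0.1 or 5, no minimum or a minimum of 200 reads, 4-fold or 1.5-fold in place of 2-fold, a ratio interval wholly beyond 2-fold, and random lists without matching. Removal of the trend of the log2 ratio with transcript length and GC content was added after seeing the data, with GC content known for 95.5% of the genes at the read minimum. The calls were tested on simulated data with Poisson noise only, drawn for the 23607 genes of the comparison of MDA-MB-435S with MCF-7. Of 50 genes changed 2.5-fold, 44 were called, as were 50 of 50 changed 4-fold and 50 of 50 changed 8-fold, 0 of 50 changed 1.5-fold and 1 of 12300 unchanged genes. The ratio interval held the true value for 95.5% of 12088 genes. Separately, 7 of 100 random lists of 30 genes lay outside the central 95% of percentiles. These lists used the observed ratios, with only the expression level simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.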

Results

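Poly(A)-selected RNA from 2 human cancer cell lines in culture was sequenced, with 1 library for MCF-7 and 1 library for MDA-MB-435S. MCF-7 is an oestrogen receptor-positive line of luminal breast carcinoma. MDA-MB-435S is a derivative of the MDA-MB-435 line, which the labels class as breast cancer and which is now widely regarded as a melanoma line. The labels name no treatment, so the design implies a single comparison, that of the transcript levels of both lines. The MCF-7 library held 14489772 reads assigned to genes and the MDA-MB-435S library 16331975. At least 1 read was assigned to 20231 genes in MCF-7 and to 20588 genes in MDA-MB-435S, and at least 50 reads to 11372 and 11845 genes. With 1 library per line, no difference has a replicate check and no p-value is given. The 95% intervals of shares, levels and folds cover counting error only. Those of medians instead describe the spread across genes, which are not independent draws. The statements below describe these 2 libraries.

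The genes with the most reads differed between the lines. KRT8, a keratin of simple epithelia, led the MCF-7 library with 233748 reads, or 1.61% of the total (exact binomial 95% interval 1.61 to 1.62%). EEF1A1, a translation elongation factor, led the MDA-MB-435S library with 301995 reads, or 1.85% (1.84 to 1.86%). KRT8, KRT18 and KRT19 together took 2.57% of the MCF-7 reads and 0.0189% of the MDA-MB-435S reads. The 10 most abundant genes held 6.33% of the reads in MCF-7 and 5.82% in MDA-MB-435S, and the 100 most abundant genes held 21.5% and 18.7%.

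MDA-MB-435S differed from MCF-7 by at least 2-fold in 5354 of the 12864 genes with at least 50 reads in the higher library. Of these, 2856 genes (22.2%) were higher in MDA-MB-435S and 2498 (19.4%) were lower, while 7510 (58.4%) lay within 2-fold. The difference reached 32-fold for 191 genes that were higher and 165 that were lower in MDA-MB-435S. Across the 12864 genes, which are not independent replicates, log2(CPM + 1) of the 2 libraries had a Pearson correlation of 0.604 and a Spearman correlation of 0.662. The genes were called by size on the log2(CPM + 1) scale, which understates the change of low genes. Scaling to library totals in place of the trimmed mean of M values (TMM) moved the median log2 ratio of all these genes from 0.025 to 0.13, upper quartile scaling moved it to -0.041, and log2 ratios are to be read against these shifts. With upper quartile scaling there were 2704 genes higher in MDA-MB-435S and 2680 genes lower in MDA-MB-435S, so the excess of higher genes depends on the scaling.

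The 10 genes furthest toward MCF-7 were KRT19, TFF1, DSCAM-AS1, SPTSSB, KRT8, SULF2, CDH1, CD24, SPINT2 and GFRA1. KRT19 had 43705 reads in MCF-7 and 17 in MDA-MB-435S, a 3134-fold difference (95% interval 1957 to 5380) between scaled levels. TFF1, a secreted peptide known as an oestrogen target, had 22693 and 14 reads (1976-fold, 1177 to 3615). DSCAM-AS1, a long non-coding RNA, had 16905 and 7 reads (2944-fold, 1428 to 7323). The 10 genes furthest toward MDA-MB-435S were SERPINE2, CD74, TNC, HLA-DRA, VIM, HLA-DRB3, MSN, HLA-DPA1, DKK3 and NOV. SERPINE2, a secreted serine protease inhibitor, had 10 reads in MCF-7 and 67398 in MDA-MB-435S (5529-fold, 3006 to 11531). TNC, the matrix glycoprotein tenascin C, had 33 and 65463 reads (1627-fold, 1159 to 2364). DKK3 had 1 read in MCF-7 and 7139 in MDA-MB-435S, so that its ratio of 5857 carried a wide counting interval of 1051 to 231367.

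**Figure D1:**
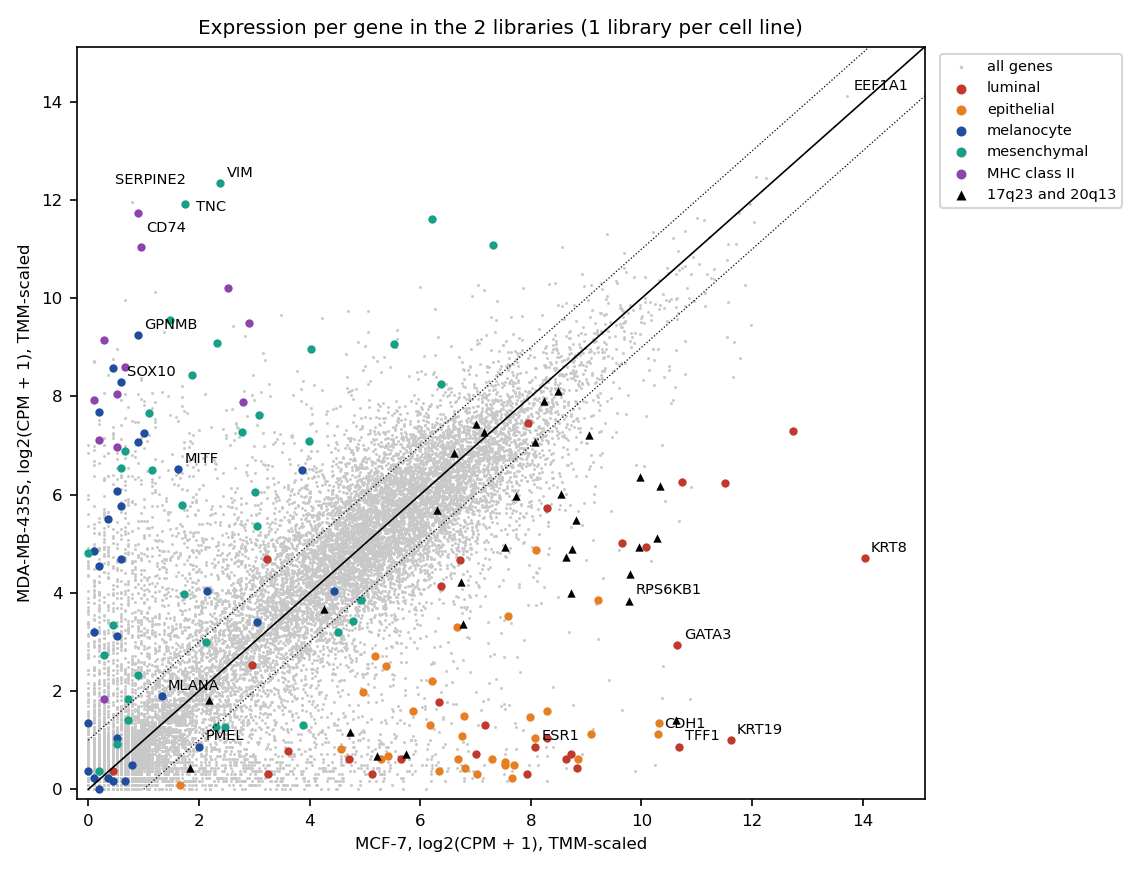
Expression per gene in the 2 libraries as log2(CPM + 1) after TMM scaling, with MCF-7 on the x axis and MDA-MB-435S on the y axis, grey points for genes, coloured points and triangles for members of gene lists, a solid line at equal levels and dotted lines at a log2 ratio of 1 in size. Luminal and epithelial genes lie mostly to the lower right and MHC class II and mesenchymal genes mostly to the upper left.

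Luminal and epithelial genes were far lower in MDA-MB-435S. Of the 29 luminal genes with enough reads, 26 were lower in MDA-MB-435S and 1 was higher, and the list median log2 ratio was -5.09 (interval -7.21 to -4.10) over 30 detected genes, below all 10000 random lists matched on expression. ESR1, the oestrogen receptor, had 3762 reads in MCF-7 and 14 in MDA-MB-435S (328-fold, 195 to 600). GATA3, a transcription factor of luminal cells, had 22392 and 113 reads (242-fold, 201 to 293), and FOXA1, which opens chromatin for the oestrogen receptor, had 6336 and 6 (1287-fold, 591 to 3509). The luminal gene that was higher in MDA-MB-435S was TBX3, named after its value was seen, with 116 reads in MCF-7 and 423 in MDA-MB-435S. Of the 31 epithelial adhesion and regulator genes with enough reads, 31 were lower in MDA-MB-435S, with a median of -5.82 (-6.72 to -4.28) that also lay below all random lists. CDH1, which encodes E-cadherin, had 17604 reads in MCF-7 and 20 in MDA-MB-435S (1073-fold, 694 to 1757). EPCAM had 6394 and 9 reads (866-fold, 456 to 1895), the desmosome gene DSP had 7523 and 20 (458-fold, 297 to 751), and KRT18 had 95509 and 2651 (43.9-fold, 42.3 to 45.7).

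Basal mammary genes went both ways. Of 16 with enough reads, 8 were higher and 4 lower in MDA-MB-435S, and the median over 23 genes was 0.25 (-0.25 to 1.98), at percentile 87.3 of random lists. It was 0.45 without a pseudocount and with the gene at 0 reads set to a floor of 3 counts. ITGA6 and MYLK were 60.0-fold (49.7 to 73.1) and 90.5-fold (64.0 to 133) higher in MDA-MB-435S. Toward MCF-7 lay ITGB4 and SFN, with 4709 and 1595 reads there against 55 and 15, together with TRIM29 and KRT17, of which TRIM29 and KRT17 were named after their values were seen.

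Mesenchymal genes were higher in MDA-MB-435S for 25 of 32 members with enough reads and lower for 6. The median over 36 genes was 3.07 (1.43 to 4.82), above all random lists, and 3.68 without a pseudocount and with the gene at 0 reads set to the floor. VIM, the intermediate filament vimentin, had 59 reads in MCF-7 and 88675 in MDA-MB-435S (1233-fold, 956 to 1620). The matrix protein SPARC had 25 and 12857 reads (422-fold, 286 to 652), CDH2, which encodes N-cadherin, had 8 and 2007 (206-fold, 104 to 477), and the collagen cross-linking enzyme LOXL2 had 56 and 9268 (136-fold, 104 to 180). The fibrillar collagen gene COL1A2 was 129.8-fold (94.04 to 185) higher in MDA-MB-435S, while COL3A1 was 9.36-fold (6.15 to 14.8) lower.

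Extracellular proteases, their inhibitors and integrins were also more often higher in MDA-MB-435S. Of 24 protease and inhibitor genes with enough reads, 13 were higher and 3 lower, and the median over 34 genes was 0.72 (-0.083 to 1.87), at percentile 99.98, and 1.33 with a minimum of 200 reads. MMP14, a membrane-bound matrix metalloprotease, had 8 reads in MCF-7 and 3204 in MDA-MB-435S (329-fold, 167 to 762), and PLAT, tissue plasminogen activator, had 8 and 2138 (219-fold, 111 to 509). The genes on the MCF-7 side, named after their values were seen, were the lysosomal proteases CTSD with 45613 and 9335 reads, CTSL1 with 1707 and 813, and CTSK with 62 and 28. With library totals the lower count was 2. Integrin subunits were higher in MDA-MB-435S for 10 of 15 genes and lower for 1, ITGB4, with a median of 0.98 (0.43 to 3.79) over 20 genes, at percentile 99.94. That median was 3.10 with a minimum of 200 reads. ITGA4 had 6 and 1785 reads (244-fold, 112 to 666) and ITGB3 had 8 and 1304 (134-fold, 67.7 to 310.4). CD44, a hyaluronan receptor, was 13.8-fold (13.2 to 14.4) higher in MDA-MB-435S.

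Melanocyte genes were higher in MDA-MB-435S for 17 of 19 members with enough reads and lower for 0. The median over 30 genes was 2.62 (0.37 to 4.90), above all random lists, and 3.49 without a pseudocount and with the 3 genes at 0 reads in a library set to the floor. It ranged from 1.33 with a pseudocount of 5 to 5.16 with a minimum of 200 reads. SOX10, a transcription factor of melanocytes and glia, had 7 reads in MCF-7 and 5304 in MDA-MB-435S (622-fold, 301 to 1547). MITF, the transcription factor that drives pigment genes, had 29 and 1546 (43.7-fold, 30.3 to 65.5), and S100B had 2 and 3491 (1432-fold, 396 to 11829). GPNMB, a melanosome glycoprotein, had 12 and 10335 (707-fold, 404 to 1368), and PLP1, a myelin protein, had 5 and 6479 (1063-fold, 455 to 3275). TYR, the first enzyme of melanin synthesis, had 1 and 140 reads (115-fold, 20.3 to 4569), MLANA had 21 and 46, and PMEL had 42 and 14, where MLANA and PMEL did not reach the read minimum of 50. TYRP1, named after its value was seen, had 10 and 7 reads.

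Neural crest genes were split, with 9 of 17 higher in MDA-MB-435S and 4 lower. Their median over 20 genes was 0.088 (-0.93 to 2.45), at percentile 68.0, and it was -0.0021 with a minimum of 200 reads and 0.52 without a pseudocount. NES, AXL and ETS1 were higher in MDA-MB-435S by 12.2-fold (11.1 to 13.5), 176-fold (108 to 309) and 264-fold (154 to 497). MSX2 was 32.3-fold (22.5 to 48.3) lower, and the other lower members, TFAP2A, L1CAM and ID3, were named after their values were seen.

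Cancer-testis genes, which are mostly silent outside germ cells and tumours, were higher in MDA-MB-435S for 12 of 14 members with enough reads. The median over 26 genes was 1.15 (0.27 to 6.48), above all random lists, and 2.78 without a pseudocount and with the 5 genes at 0 reads in a library set to the floor. It ranged from 0.48 with a pseudocount of 5 to 6.61 with a minimum of 200 reads. MAGEC2 had 5 and 7370 reads in MCF-7 and MDA-MB-435S (1209-fold, 518 to 3725), MAGEA3 had 4 and 5838 (1197-fold, 467 to 4396) and MAGEA12 had 2 and 2920 (1198-fold, 331 to 9895). The member on the MCF-7 side was TEX14, with 185 and 20 reads, named after its value was seen. Close copies within the MAGE family can share reads, and how such reads were counted is not given, so single MAGE values are uncertain.

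MHC class II antigen presentation genes had the highest median of the 27 lists. For these, 11 of 11 genes with enough reads were higher, with a median of 7.62 (6.46 to 8.87) over 12 genes, above all random lists. CD74, the invariant chain, had 12 reads in MCF-7 and 58107 in MDA-MB-435S (3973-fold, 2274 to 7689), HLA-DRA had 13 and 35819 (2260-fold, 1322 to 4246) and HLA-DPA1 had 3 and 9654 (2640-fold, 903 to 12804). The HLA-DRB genes are close copies of each other, so their separate values are uncertain. For MHC class I presentation, 13 of 18 genes were higher and 0 lower, with a median of 1.98 (0.93 to 4.68), above all random lists. The immunoproteasome gene PSMB8 had 32 and 2080 reads (53.3-fold, 37.7 to 78.2), and NLRC5, an activator of class I genes, had 17 and 1094 (52.8-fold, 32.8 to 91.0). Interferon-stimulated genes went both ways. Of 37 with enough reads, 13 were higher, 10 lower and 14 within 2-fold, with a median of 0.11 (-0.76 to 1.29) over 39 genes at percentile 62.7. IFI16 and MX2 were higher in MDA-MB-435S, with 2419 and 958 reads against 3 and 10, while IFI27 and IFITM2 were lower, with 4 and 10 reads against 549 and 663.

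**Figure D2:**
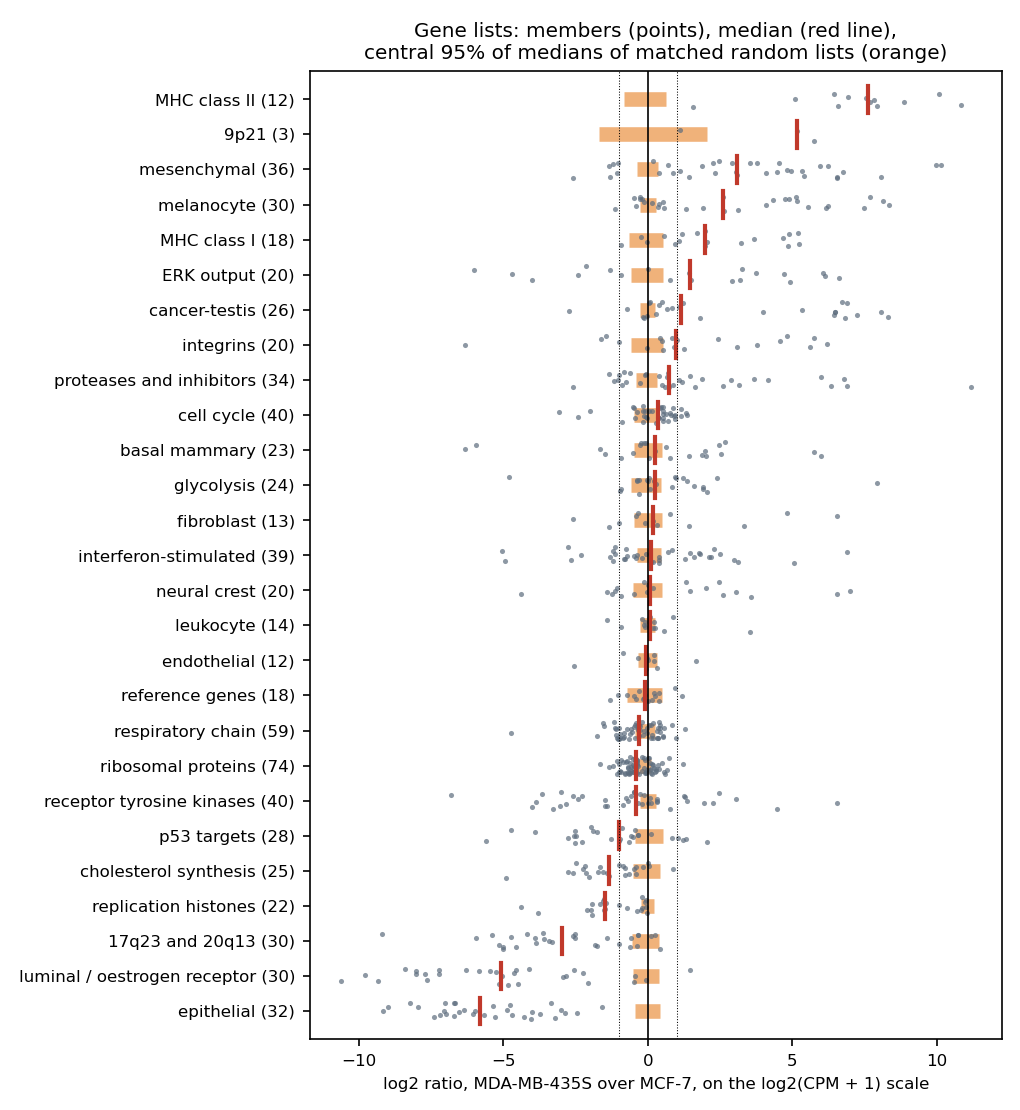
Log2 ratio of MDA-MB-435S over MCF-7 on the log2(CPM + 1) scale for the detected genes of each of the 27 gene lists, with points for genes, a red line for the list median, an orange bar for the central 95% of medians of matched random lists and dotted lines at a log2 ratio of 1 in size. The medians run from -5.82 for epithelial genes to 7.62 for MHC class II genes.

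Receptor tyrosine kinases went both ways between the lines. Of 29 with enough reads, 9 were higher and 14 lower in MDA-MB-435S, with a median of -0.41 (-1.42 to 0.11) over 40 genes at percentile 0.200, and -0.92 without a pseudocount. RET had 2566 reads in MCF-7 and 11 in MDA-MB-435S (284-fold, 159 to 570), and EPHA4 had 610 and 30. AXL had 16 and 3439 reads, DDR2 had 10 and 635 (52.1-fold, 28.1 to 109), and EGFR had 41 and 352 (7.04-fold, 5.09 to 9.99). ERBB2 was 2.72-fold (2.48 to 2.99) lower in MDA-MB-435S. Genes known as output of the ERK pathway were higher in 11 of 20 cases and lower in 6, with a median of 1.46 (-1.32 to 3.74) at percentile 99.99. SPRY2, a feedback inhibitor of the pathway, had 16 and 3554 reads (182-fold, 112 to 319), and the transcription factors ETV1 and ETV5 were 149-fold (83.2 to 299) and 109.7-fold (74.2 to 169.7) higher. The immediate early gene FOS went the other way, with 15861 reads in MCF-7 and 280 in MDA-MB-435S (69.0-fold, 61.3 to 78.0).

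Known p53 targets were lower in MDA-MB-435S for 14 of 28 genes and higher for 4, with a median of -0.98 (-2.28 to -0.44), below all random lists. PHLDA3 had 1010 reads in MCF-7 and 9 in MDA-MB-435S (137-fold, 71.8 to 300.0), and BTG2 had 658 and 38. PPM1D, with 5868 and 255 reads (28.0-fold, 24.7 to 31.9), is also on the list of genes from 17q23. The higher members, named after their values were seen, were ZMAT3, POLH, GADD45A and TNFRSF10B. TP53 itself had 2587 and 3263 reads, a scaled ratio of 1.03 (0.982 to 1.09) whose direction turned under upper quartile scaling. Cell cycle genes lay within 2-fold for 33 of 40 members, with 4 higher and 3 lower and a median of 0.37 (-0.054 to 0.54) at percentile 98.5, and the higher count was 7 with library totals. MKI67, a marker of cycling cells, had a ratio of 0.890 (0.857 to 0.923). CCND1, which encodes cyclin D1, was 5.30-fold (5.14 to 5.47) lower in MDA-MB-435S, as were CDC25C and GINS2 by 12.8-fold and 4.10-fold. CENPF was 2.61-fold (2.42 to 2.82) higher, and TPX2, UBE2C and TYMS, named after their values were seen, were the other higher members.

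Cholesterol synthesis genes were lower in MDA-MB-435S for 13 of 24 members with enough reads and higher for 0. The median over 25 genes was -1.34 (-2.03 to -0.64), below all random lists. TM7SF2 was 42.0-fold (30.7 to 59.0) lower, MVD 7.22-fold (6.29 to 8.31), CYP51A1 6.13-fold (5.61 to 6.71) and DHCR7 5.67-fold (5.37 to 5.99). Glycolysis genes were higher for 8 of 24 and lower for 1, with a median of 0.24 (-0.31 to 1.34) at percentile 89.3. LDHB, a lactate dehydrogenase subunit, had 22 reads in MCF-7 and 10812 in MDA-MB-435S (403-fold, 266 to 644), the glucose transporter SLC2A3 was 6.23-fold (4.74 to 8.32) higher and the kinase PDK1 4.45-fold (3.74 to 5.31) higher. The lower gene was ALDOC, with 516 and 6 reads.

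Respiratory chain and ribosomal protein genes lay mostly within 2-fold. Of 59 respiratory chain and ATP synthase genes, 1 was higher, 10 were lower and 48 lay within 2-fold, with a median of -0.32 (-0.55 to -0.027) at percentile 10.3. The lower count was 6 with library totals and 14 with upper quartile scaling, and the higher count was 2 with library totals or the median of ratios. COX6C, a cytochrome c oxidase subunit, was 27.2-fold (25.7 to 28.8) lower in MDA-MB-435S, NDUFB1 3.45-fold and UQCRB 2.94-fold lower. The higher gene was SDHD, named after its value was seen, with 817 and 2433 reads. Of 74 ribosomal protein genes, 1 was higher, 6 were lower and 67 lay within 2-fold, with a median of -0.39 (-0.51 to -0.21) at percentile 5.99. The lower count was 3 with library totals and 10 with upper quartile scaling. RPL13 was 3.14-fold (3.07 to 3.22) lower and RPLP2 2.31-fold (2.22 to 2.41) higher. Ribosomal protein genes have close copies that can share reads, so these single values are uncertain. Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, were lower for 8 of 8 members with enough reads. Their median over 22 genes was -1.47 (-1.92 to -0.21), below all random lists, and -1.98 without a pseudocount and with the 3 genes at 0 reads in a library set to the floor. It ranged from -0.46 with a pseudocount of 5 to -2.87 with a minimum of 200 reads. HIST1H2BD had 932 and 38 reads and HIST2H2BE had 1633 and 126. Because the RNA was poly(A)-selected, these values do not give the total level of these messages in either line.

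Genes of the 17q23 and 20q13 regions, known to be amplified in MCF-7, were lower in MDA-MB-435S for 20 of 28 members with enough reads and higher for 0. The median over 30 genes was -2.96 (-3.92 to -1.40), below all random lists. RPS6KB1, which encodes the ribosomal S6 kinase, had 12240 reads in MCF-7 and 227 in MDA-MB-435S (65.7-fold, 57.6 to 75.3). BCAS3 was 44.5-fold (39.9 to 49.8) and TRIM37 36.7-fold (33.7 to 39.9) lower, and SULF2, a sulfatase of heparan sulfate, had 21968 and 28 reads (956-fold, 661 to 1440). The regions differed, since on 17q23 12 of 12 listed genes with enough reads were lower and on 20q13 8 of 16, with the other 8 within 2-fold. Between the listed genes lie others that are not on the list. On 17q23 there were 14 of these with enough reads, from TRIM37 to TLK2, of which 9 were lower and 1 higher in MDA-MB-435S. On 20q13 there were 19, from ZMYND8 to PFDN4, of which 3 were lower and 5 higher. The genes of the 9p21 region, part of which is known to be deleted in MCF-7, were higher in MDA-MB-435S in 3 of 3 cases, with log2 ratios from 1.10 to 5.76 and a median of 5.15, at percentile 99.96. CDKN2A had 7 reads in MCF-7 and 1370 in MDA-MB-435S (161-fold, 77.7 to 400.1), MTAP had 35 and 2108 (49.4-fold, 35.4 to 71.1) and CDKN2B had 74 and 213 (2.36-fold, 1.805 to 3.12). The CDKN2B level in MCF-7, 5.31 CPM (4.17 to 6.67), lay above the floor of 0.215 CPM. So did the MTAP level there, 2.51 CPM (1.75 to 3.49). CDKN2A, at 0.502 CPM in MCF-7, had an interval of 0.202 to 1.04 that reached the floor. The source of the MTAP and CDKN2A reads in MCF-7 was not tested.

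Most leukocyte and endothelial markers had under 50 reads in both libraries, while 7 of 13 detected fibroblast markers reached that number. Of 14 detected leukocyte markers, 2 had enough reads, CD68 with 61 and 1048 reads (14.1-fold higher in MDA-MB-435S, 10.9 to 18.6) and CORO1A with 186 and 74. The leukocyte median was 0.060 (-0.21 to 0.58) at percentile 67.3, and its sign turned to -0.088 without a pseudocount and with the gene at 0 reads set to the floor. Among 12 endothelial markers, 3 had enough reads, of which ROBO4 was higher in MDA-MB-435S and EGFL7 lower, with a median of -0.051 (-0.33 to 0.22) at percentile 38.4. Fibroblast markers were higher for 4 of 7 genes and lower for 2, with a median of 0.18 (-0.99 to 3.32) over 13 genes at percentile 80.2, or 0.98 without a pseudocount and with the gene at 0 reads set to the floor. FAP had 8 and 250 reads, and THY1 had 0 in MCF-7 and 463 in MDA-MB-435S. On the fibroblast list, 7 genes are also on another list.

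Reference genes lay within 2-fold for 15 of 18 members, with a median of -0.10 (-0.39 to 0.25) at percentile 54.9, which became 0.011 when scaled to library totals. GAPDH had a ratio of 1.15 (1.14 to 1.16) and ACTB of 1.32 (1.31 to 1.34). B2M, which belongs to MHC class I, was 2.28-fold (2.22 to 2.34) higher in MDA-MB-435S, while YWHAZ and GUSB were 2.46-fold and 2.07-fold lower. When scaled to library totals, GUSB had a log2 ratio of -0.93 and was no longer called.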

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

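No called named gene and no list median of at least 1 in size changed sign under the alternatives run. Across lists and settings, 232 medians stayed within the interval of the main value (for 9p21, the range of its 3 genes) and 11 left it. Counts of list members higher or lower moved by over 1.5 times, or to or from 0, in 64 cases and by less in 530. Log2 ratios of named genes were set against the counting interval of the fold without a pseudocount. In 139 cases the value lay outside that interval and had also shifted by more than the distance from its centre to its limits. The other 715 cases met at most 1 of these conditions. Scaling moved the lower count of glycolysis genes from 1 to 2 with the upper quartile, and the higher and lower counts of reference genes from 1 and 2 to 2 and 1 with library totals. The count of genes higher in MDA-MB-435S was 2856, with 1313 at 4-fold and 4082 at 1.5-fold. The count of genes lower in MDA-MB-435S was 2498, with 1092 at 4-fold and 3755 at 1.5-fold. The other settings kept the counts within 1.5 times, from 2239 higher and 1948 lower with a pseudocount of 5 to 3126 higher with library totals and 2768 lower without a read minimum. A pseudocount of 0.1 moved the median log2 ratio of epithelial genes to -6.77, of MHC class II genes to 9.06 and of histone genes to -1.98, and one of 5 moved them to -4.23, 5.81 and -0.46. With a pseudocount of 0.1 and of 5, melanocyte genes had medians of 3.95 and 1.33, cancer-testis genes of 2.81 and 0.48, receptor kinases of -0.75 and -0.14, basal genes of 0.42 and 0.091 and fibroblast genes of 0.70 and 0.042, within the intervals of their main values. These shifts follow from the construction, since a pseudocount acts most on genes near 0. A minimum of 200 reads left fewer genes per list and gave 5.16 for melanocyte, 6.61 for cancer-testis, -2.87 for histone and 4.07 for fibroblast genes, with 4 fibroblast genes left. The leukocyte value of 3.54 and the endothelial value of -2.56 then were those of a single gene each, CD68 and EGFL7. The same minimum gave within the main intervals 3.10 for integrins, 1.33 for proteases, 0.94 for basal and 0.38 for interferon-stimulated genes. Interferon-stimulated genes had a median of 0.21 with library totals and 0.040 with upper quartile scaling. Removing the length and GC trend gave -0.12 for respiratory chain and -0.24 for ribosomal protein genes. Without a pseudocount the medians of neural crest genes, receptor kinases and endothelial markers were 0.52, -0.92 and -0.16. Under the other settings the neural crest median ranged from -0.0021 to 0.35 and the reference gene median from -0.17 to 0.011, so neither has a settled direction. Without matching on expression, the percentile of respiratory chain genes went from 10.3 to 0.1 and that of ribosomal protein genes from 5.99 to 0, and the cause was not tested. Summing against choosing rows of the same gene was not run, because the tables hold 1 row per gene. No paired analysis was possible because each line has 1 library, and for the same reason no replicate could be left out. Depth limits genes under 50 reads in the higher library, which were not called, and with 1 library per line no value has a check against differences between cultures or library preparations.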

Other observations

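Gene families were looked at after the counts had been seen, 16 in all, so the most extreme of them were picked from several. HOX genes, the transcription factors of body-axis patterning, were higher in MDA-MB-435S for 16 of 22 members with enough reads and lower for 1, HOXA5, and their median log2 ratio over 38 detected genes was 1.06 (0.34 to 1.70), above all 10000 random lists. HOXC10 had 14 reads in MCF-7 and 729 in MDA-MB-435S (42.7-fold, 25.3 to 78.5) and HOXB2 had 4 and 250. Metallothioneins, which bind zinc and copper, were higher for 5 of 5 genes, with a median of 1.56 (0.40 to 6.50) at percentile 99.95. MT2A was 10.8-fold (9.66 to 11.99) higher, and MT1E had 1 and 1627 reads, although close copies in this family can share reads. Laminins were higher for 5 of 10 and lower for 1, LAMA5. Their median over 12 detected genes was 0.82 (-0.51 to 2.03), an interval that includes 0, at percentile 99.2. LAMA4 had 5 and 2585 reads and LAMB1 had 96 and 5874. IGF-binding proteins went both ways, with 4 of 6 lower and 2 higher and a median of -2.26 (-8.01 to 6.93) at percentile 0.07. IGFBP4, IGFBP2 and IGFBP5 had 5923, 1697 and 1078 reads in MCF-7 against 11, 3 and 36, while IGFBP7 had 17 against 4577. Keratins were lower for 8 of 15 with enough reads and higher for 4. Their median over 44 detected genes was -0.21 (-0.72 to -0.059) at percentile 0.11. ABC transporters, glutathione S-transferases, claudins, and chemokines and interleukins had medians between percentiles 38.1 and 48.7. All family medians include detected genes under 50 reads, which the pseudocount pulls toward 0, so such a median can hide members that differ. Of 9 claudins with enough reads, 5 were lower and 2 higher in MDA-MB-435S. CLDN3, CLDN4 and CLDN7 had 2789, 4348 and 2574 reads in MCF-7 against 3, 34 and 8, while CLDN11 had 18 against 327.

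Several genes that many cell types express were far lower in a single line. PRDX1, a peroxiredoxin that removes hydrogen peroxide, had 9434 reads in MCF-7 and 63 in MDA-MB-435S (183-fold, 143 to 238). GSTP1, a glutathione transferase, had 13 and 5456 reads (344-fold, 201 to 647), and GPX1, a glutathione peroxidase, had 5 and 2401 (394-fold, 169 to 1214). These genes were picked after their values were seen, and no explanation for them was tested.

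The tests of swapped labels, of mixed cultures, of 17q23 and 20q13 taken apart and of carry-over were chosen after the result was seen. The tests of length and GC content, of both regions pooled and of windows were added after the data had been seen but before their own results were. The first pattern is the high level of melanocyte genes in the library labelled MDA-MB-435S, for 17 of 19 with enough reads. PMEL, MLANA and TYRP1 did not reach the read minimum. A swap of the 2 labels would put the luminal genes in that library, yet their median log2 ratio was -5.09 and MTAP, known to be deleted in MCF-7, was 49.4-fold higher there, which argues against a swap. A mostly epithelial culture with a minority of melanocytic cells would keep epithelial genes near their MCF-7 level, and their median of -5.82 (-6.72 to -4.28) argues against that too. A mix of melanocytic cells with mesenchymal cells stays open, since 17 melanocyte genes were higher but a pooled library cannot show whether they share cells with VIM and TNC. A biological difference between the lines stays open and was not tested.

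The second pattern is the high level in MCF-7 of the listed genes of 17q23, 12 of 12, and of 20q13, 8 of 16. Length and GC content do not account for all of it, because the list median was -2.89 (-3.75 to -1.58) after their trend was removed. Extra copies would also raise the unlisted genes in between. Their pooled median of -0.56 (-1.70 to 0.089), at percentile 8.72 of random blocks of neighbouring genes, left this open, but on 17q23 it was -1.82 (-2.66 to -0.46) at percentile 0.350, while on 20q13 it was 0.089 (-0.67 to 1.45) at percentile 55.5. Higher copy number may therefore contribute on 17q23. On 20q13 it cannot be told apart from regulation of the single genes, because the interval of the genes in between is wide. A median over the whole block also cannot test shorter stretches within it. Of the 3 lower unlisted genes there, LINC00494 and PARD6B lie next to lower listed genes among those with enough reads, and ATP9A does not. The lower genes of 20q13 lay mostly in runs of neighbours with enough reads. NCOA3, SULF2, LINC00494 and PREX1 formed one run, PARD6B and BCAS4 another, and ZNF217, BCAS1, CYP24A1 and PFDN4 a further one. These runs were seen after the result, and whether they reflect copy number was not tested.

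A related hypothesis is that neighbouring genes differ together across the autosomes. Of 11988 overlapping windows of 15 neighbouring genes, 1377 had a median log2 ratio of at least 1 in size, against at most 209 in 100 shuffles of gene order. The lowest window ran from CLTC to BRIP1 with a median of -3.41. It lies inside the 17q23 block above and holds listed genes such as RPS6KB1 and BCAS3, so it is not a separate observation. Outside that block, a low window from LRIG2 to SIKE1 held NRAS and CSDE1 with a median of -2.37. A low window on chromosome 17 from AMZ2P1 to SLC16A6 had a median of -2.25, with 13 of 15 genes lower. Among the high ones, the window from HLA-DRB1 to HLA-DPA1 had a median of 5.23 and that from HERPUD1 to KIFC3, with 15 of 15 genes higher, 2.19. This is consistent with regional effects such as copy number, but shared regulation of neighbouring genes, as in the HLA cluster, may give the same count and was not separated from it.

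The third pattern is the far smaller number of reads that some abundant genes of each line had in the other library. It was taken over genes with at least 10000 reads and a log2 ratio of at least 5 in size. This choice leaves out residual shares much above 3%. Carry-over of reads between libraries would take a like share of every gene. The residual share ranged from 0.0312% for SPTSSB to 2.999% for APPBP2 among 23 genes abundant in MCF-7, and from 0.0181% for SERPINE2 to 2.89% for S100A6 among 18 genes abundant in MDA-MB-435S. The ratio of highest to lowest was at least 96.1 in both directions, so carry-over could not be the whole source for all of these genes. A wide range was likely, since the set holds genes with many reads in the other library, such as KRT18 with 2651 and FN1 with 1020. The range does not show whether the few reads of the genes with the lowest shares are carry-over. A carry-over up to the lowest of these shares stays possible, and at that level a few reads of KRT19 or CD74 in the other line say nothing of their expression there.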
